A study of Homo sapiens with 4 samples.

How the data were processed

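HaCaT cells, a spontaneously immortalised human keratinocyte line, had been transfected with a precursor of the microRNA miR-483-3p or with a negative control precursor, and total RNA was taken at 48 h and extracted with TRIzol, per the labels. The labels name 2 pairs of RNA extracts, numbered 1 and 2, each pair holding 1 extract of either transfection. Each pair was hybridised to 2 arrays of 2 colours with the dyes swapped, which gives 4 arrays. The labels do not say whether the extract pairs came from separate cultures, so the p-values measure the spread between these 2 pairs, which may be technical.

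The deposited values are 1 log ratio per feature and array, made by the authors, with no missing value among 27648 features. Background correction, normalization, filters and scanner are not given in the sources used here. Every column had a mean of 0 over all features, and the column medians lay between −0.0059 and 0.0148, so each array had been centred by the authors in some way. The base of the deposited log ratios is not given. Base 10 would exceed the range of a 16-bit scanner for the largest values, so the log ratios made and deposited by the authors were taken as log2, the usual choice. Every fold stated here holds only for that base. No channel intensities were used here. Dim or saturated spots could therefore not be left out, and the number of arrays limits the precision.

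The sign of the ratios is not given either. By the rule set before the data were examined, the arrays would have been turned by their dye labels had opposite dye orientations correlated below 0. They correlated above 0 (r = 0.395 to 0.426 across 14533 genes, against 0.637 and 0.583 within an orientation, genes not being independent replicates), so the values were used as they are. A positive correlation can come from ratios that the authors had already turned or from dye bias that does not follow the RNA. For 1721 genes with exactly 2 probes, the mean of the 4 arrays correlated between the probes (r = 0.374, rho = 0.310), and the part that changed with the dye orientation hardly did (r = 0.031, rho = 0.064). The ratio was taken as miR-483-3p over control. This sign is likely at most. It rests on lower values of MKI67, YAP1 and MAPKAPK2, which the submitting group has reported as miR-483-3p targets, possibly from these same samples. Other reported targets do not bear it out. CDC25A, also reported by that group, was at −0.01, and the 2 probes of MAPKAPK2 disagreed, at −1.22 and 0.07. Of 4 targets reported elsewhere, 0 passed as lower and the median was 0.14. If the sign is opposite, every "higher" becomes "lower" and the reverse.

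Genes were named from the platform annotation. Of the features, 17711 had 1 gene symbol, 0 had several and 9937 had none. Names were brought up to date through a RefSeq gene table of GRCh38.p14, which matched 14721 features by accession, 1814 by current symbol and 1085 by older symbol; 91 kept the symbol of the annotation. No coordinates were used, because the annotation names no genome build. Probes of a gene were averaged, which gave 14533 genes, 2067 of them with more than 1 probe. ACTB had 321 spots and GAPDH 272. Where probes of a gene named by the rule below differed by more than 0.3 or in sign, their values are given.

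The dye-swapped arrays of an extract pair were averaged first, since they hold the same RNA, so n = 2, and a constant dye effect cancels in each mean if the ratios had been turned. The log ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes; prior degrees of freedom 3.68, prior SD 0.111), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SDs are those of the 2 extract-pair means. All 34 gene lists were fixed before the data were examined. Of these, 32 had at least 5 measured genes and were tested with limma's camera at a correlation of 0.01, with fry as a companion, adjusted over the lists. Named genes were taken by a rule fixed at the same time: among genes past the threshold with the same sign on all 4 arrays, the 12 largest increases and the 12 largest decreases; CDC25A, MAPKAPK2, MKI67, YAP1, BBC3, SMAD4, CTNNBIP1 and IGF2 whatever their values; and, of each list, the 4 members with the largest size of log ratio among those with the same sign on all 4 arrays. Genes outside this rule were chosen after their values were seen, and are said to be.

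The test was tried on simulated data of 14533 genes with 200 changed genes, 100 at each of 2 sizes, and spreads drawn from the fitted prior. It recovered 98 of the 100 genes with a log ratio of size 1 and 33 of the 100 with a size of 0.5, and made 12 false calls, 8.4% of its calls. The simulation had far fewer changed genes than the 2090 that passed in the data, and no offset shared by both extract pairs. Its shares of recovered genes and false calls therefore need not hold for the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

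The alternatives were another centring or scaling of the arrays, all 4 arrays in 1 fit with and without a block for the extract pair, a single dye orientation, single probes, robust eBayes, other thresholds, leaving out either extract pair and, for the lists, an estimated correlation. The replicate numbers pair the arrays because the labels give the same extracts for the same number. Between opposite orientations, arrays of the same extracts correlated at r = 0.411 and 0.426 and arrays of different extracts at 0.415 and 0.395. A planned test of genes with a miR-483-3p seed site was not run, because 3' UTR sequences were not used here.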

Results

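The arrays compared HaCaT keratinocytes 48 h after transfection with a miR-483-3p precursor with cells given a control precursor. The comparison asks which transcripts differ when this microRNA, encoded in an intron of IGF2, is overexpressed. The 4 arrays hold 2 pairs of RNA extracts in both dye orientations. Values are log ratios of miR-483-3p over control as the authors deposited them, with base 2 assumed and this sign likely at most. They are given as the mean ± SD of the extract pairs (n = 2 throughout).

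In the cells given miR-483-3p, SERPINB7, a serine protease inhibitor of the epidermis, had the largest decrease (−2.40 ± 0.11, or 5.29-fold lower). PGM2L1, which makes glucose 1,6-bisphosphate, had the largest increase (2.24 ± 0.13, or 4.73-fold higher). Among the 12 largest decreases were RRM2, a subunit of ribonucleotide reductase (−1.86 ± 0.06), and the spindle checkpoint kinase gene BUB1 (−1.60 ± 0.20). They also included the glycolytic enzyme gene PGAM1 (−1.89 ± 0.04), the gap junction gene GJA1 (−1.83 ± 0.03) and the galectin gene LGALS1 (−1.76 ± 0.16). The other members of that group were EI24 (−2.18 ± 0.02), ATP6V1B2 (−1.78 ± 0.0033), EPB41L4A-AS1 (−1.60 ± 0.21), PRXL2A (−1.59 ± 0.05), SLC49A4 (−1.58 ± 0.09) and ECHDC3 (−1.54 ± 0.08). Among the 12 largest increases were 3 genes of mucins, the glycoproteins of epithelial surfaces: MUC4 (1.80 ± 0.06), MUC16 (1.76 ± 0.27) and MUC20 (1.75 ± 0.03). ISYNA1, which catalyses the committed step of inositol synthesis, reached 1.70 ± 0.18, and the heme oxygenase gene HMOX1 1.49 ± 0.22. The histone genes H2BC12 (1.61 ± 0.05) and H1-2 (1.51 ± 0.03), the keratin gene KRT23 (1.58 ± 0.04), ATP6AP1 (1.49 ± 0.18), IDH1 (1.45 ± 0.17) and UBE2V1 (1.43 ± 0.0051) complete the group. Each of these 24 genes had an adjusted p of 0.00542 by limma and the same sign on all 4 arrays. ATP6AP1 and ATP6V1B2, both of the vacuolar proton pump, changed in opposite directions.

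**Figure D1:**
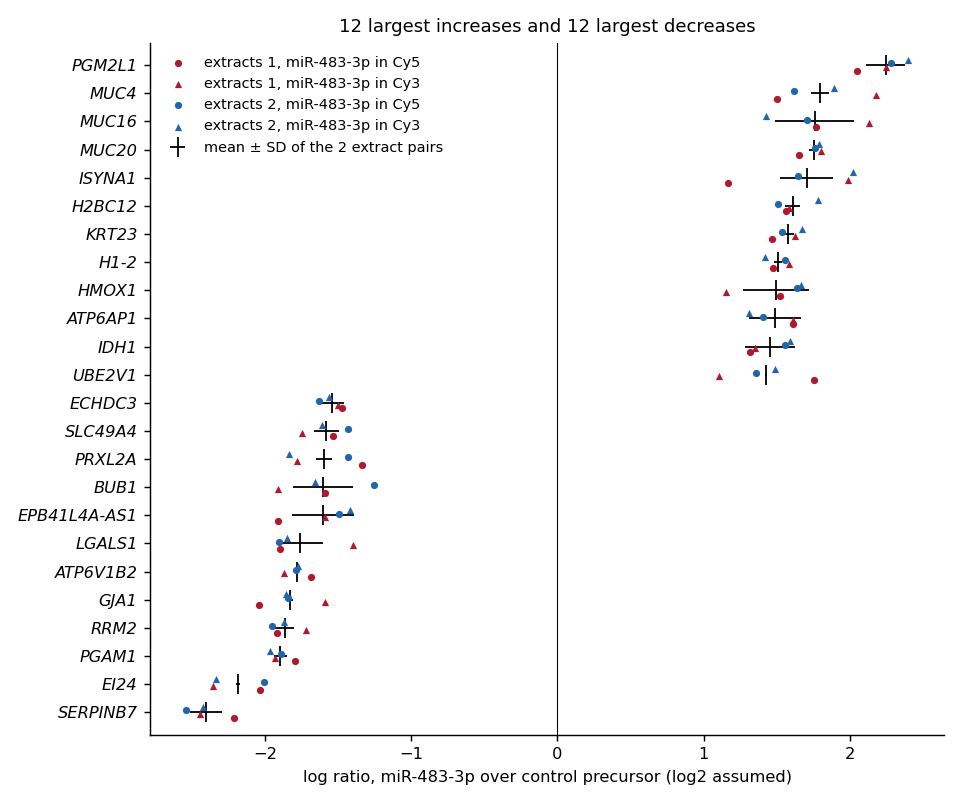
Log ratio of miR-483-3p over control (x axis, log2 assumed) for the 12 genes with the largest increase and the 12 with the largest decrease. Coloured symbols are the 4 arrays (colour for the extract pair, circles for miR-483-3p in Cy5 and triangles in Cy3), and the black bar is the mean ± SD of the 2 extract pairs; for SERPINB7 the arrays lie between −2.54 and −2.21, and for PGM2L1 between 2.05 and 2.40.

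Of 14533 genes, 1061 were higher and 1029 lower past an adjusted p of 0.05 by limma, and 2038 of these 2090 had the same sign on all 4 arrays. The smallest size of log ratio that passed was 0.318 and the median size was 0.518. Repeated control spots differed by 0.362 (ACTB) and 0.343 (GAPDH) between parts of the arrays, in both dye orientations, as described below. The p-values measure the spread between the extract pairs and do not cover an offset that both pairs share. Nor does the rule of the same sign. At least 2-fold changes with the same sign on every array were seen for 64 genes that were higher and 129 that were lower, and 190 of these 193 also passed the test. The means of the extract pairs correlated across genes (r = 0.714, rho = 0.627), genes not being independent replicates. With only the arrays of 1 dye orientation, the counts were 569 higher and 807 lower (miR-483-3p in Cy5) and 557 higher and 463 lower (in Cy3).

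**Figure D2:**
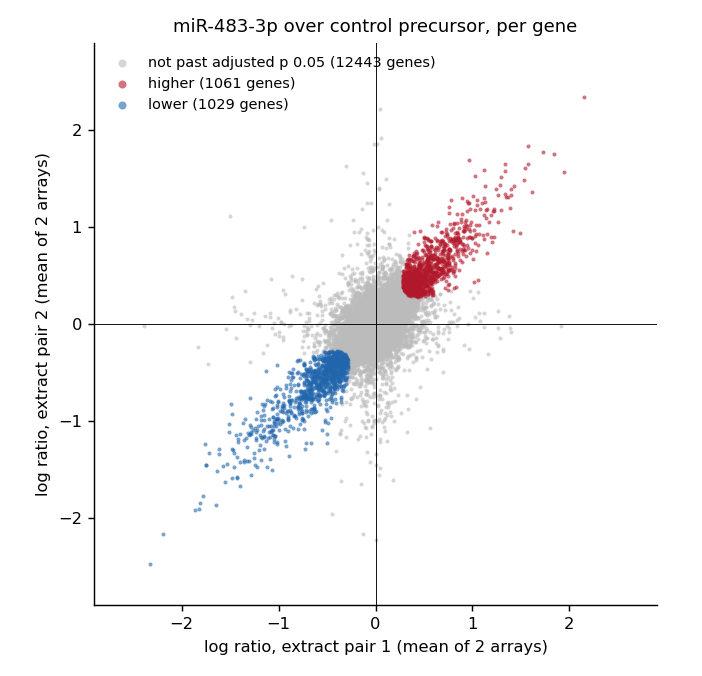
Each point is 1 of 14533 genes, with its log ratio in extract pair 1 (x axis) and extract pair 2 (y axis), each the mean of 2 dye-swapped arrays. The 1061 genes past adjusted p as higher and the 1029 as lower lie along the diagonal, while genes far from 0 in a single pair were not called.

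Genes of cell division were lower. All 29 measured genes of the list for G2/M and mitosis passed as lower (29 adjusted over the list alone), with a median of −1.16 and an adjusted p by camera of 1.60e-22. With an estimated correlation the list did not pass (adjusted p = 0.966 on the extract-pair means, 0.51 on 4 arrays). That version of camera has 1 residual degree of freedom on the extract-pair means and few on 4 arrays. It can therefore hardly pass any list. The correlation of this list was estimated at 0.5074 on the extract-pair means and 0.4354 on 4 arrays, above the 0.01 assumed. Were it that high, the p-value at 0.01 would be too small. The estimates themselves rest on few residual degrees of freedom. CCNB1, the mitotic cyclin B, was 2.83-fold lower (SD 0.37 on the log2 scale). CDK1, its kinase partner, was at −1.41 ± 0.04, and PTTG1, the securin, at −1.45 ± 0.23. The probes of PTTG1 may also detect its near copy PTTG3 and gave −1.45 each. For G1/S and DNA replication, 18 of 28 genes were lower and 0 higher (22 lower adjusted over the list alone), with a median of −0.60 and an adjusted p by camera of 4.73e-12 (adjusted p = 0.966 with an estimated correlation, 0.51 on 4 arrays). Its correlation was estimated at 0.0952 on the extract-pair means and 0.095 on 4 arrays, also above 0.01. RRM1, the large subunit of ribonucleotide reductase, was at −1.16 ± 0.0082, CDC45, part of the replicative helicase, at −1.12 ± 0.15, and MCM2, another part of it, at −1.10 ± 0.24. Among D-type cyclins, CDKs and CDK inhibitors, 2 of 14 genes were higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.332 by camera). CCND1, the gene of cyclin D1 (0.42 ± 0.03, probes 0.59 and 0.26), and the inhibitor gene CDKN1C (0.70 ± 0.25) were higher, and the inhibitor genes CDKN2B (−0.54 ± 0.03) and CDKN2C (−0.38 ± 0.02) lower.

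Replication-dependent histones are made in S phase and packaged with new DNA. Of 13 measured genes of their list, 9 passed as higher and 0 as lower (10 higher adjusted over the list alone), with a median of 0.94 and an adjusted p by camera of 3.39e-06 (adjusted p = 0.966 with an estimated correlation, 0.51 on 4 arrays). Over all 60 measured genes with symbols of such histones, a set chosen after the values were seen, 19 were higher and 2 lower and the median was 0.17. On the list, besides H2BC12 and H1-2, the largest were H2BC5 (1.11 ± 0.04, with probes from 0.80 to 1.45) and H2AC8 (1.10 ± 0.10). Histone genes of 1 class are near-identical, so a probe may report several of them.

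Among inflammatory cytokines and NF-kB targets, 7 of 21 genes were lower and 1 higher (11 lower and 1 higher adjusted over the list alone), with a median of −0.26 and an adjusted p by camera of 0.00824. The chemokine genes CXCL1 (−1.53 ± 0.27), CCL20 (−0.98 ± 0.36) and CXCL8 (−0.73 ± 0.14) were lower, and TNFAIP2, which TNF induces, was higher (0.83 ± 0.07). Among TGF-beta and SMAD target genes, 6 of 16 were lower and 0 higher (8 lower and 1 higher adjusted over the list alone), with a median of −0.19 and an adjusted p by camera of 0.0137. The matrix glycoprotein gene THBS1 (−0.94 ± 0.21), the transcription regulator gene ID2 (−0.85 ± 0.05), the pathway inhibitor gene SMAD7 (−0.59 ± 0.05) and CDKN2B were the largest. For fatty acid synthesis, 4 of 9 genes were higher and 0 lower (6 higher adjusted over the list alone), with a median of 0.31 and an adjusted p by camera of 0.0215. They were SREBF1, the lipogenic transcription factor gene (1.33 ± 0.03), FASN, the fatty acid synthase gene (0.65 ± 0.17), the desaturase gene SCD (0.39 ± 0.01) and ACLY, whose enzyme makes cytosolic acetyl-CoA (0.35 ± 0.01). These 3 lists did not pass with an estimated correlation (adjusted p = 0.966 by camera, and 0.51 on 4 arrays). On the extract-pair means it was estimated at −0.0286 for inflammation, 0 for TGF-beta and −0.1111 for fatty acid synthesis. These estimates lie below 0.01, so the loss did not come from a larger estimated correlation. With 1 residual degree of freedom, each estimate rests only on how the genes split between the extract pairs. It cannot show whether the genes are correlated. Without the 8 runs of features described with the control spots, the 3 lists did not pass camera either. Their medians were then −0.22 for inflammation (adjusted p = 0.0634 by camera), −0.24 for TGF-beta (0.106) and 0.28 for fatty acid synthesis (0.108).

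Of 4 genes that the submitting group has reported as miR-483-3p targets, 3 were lower (3 adjusted over the list alone). This list may rest on these samples and is not independent evidence of the direction. The proliferation marker gene MKI67 was at −1.54 ± 0.19, YAP1, a transcriptional coactivator of the Hippo pathway, at −1.10 ± 0.09 and the kinase gene MAPKAPK2 at −0.58 ± 0.04. The probes of MAPKAPK2 disagreed, at −1.22 and 0.07. The fourth gene, the phosphatase gene CDC25A, was at −0.01 ± 0.08 and did not pass (adjusted p = 0.933 by limma). None of 4 targets reported elsewhere passed (0 adjusted over the list alone). BBC3 was at 0.23 ± 0.14, SMAD4 at 0.07 ± 0.06, GDF3 at 0.20 ± 0.10 and CTNNBIP1 at −0.09 ± 0.31, its probes at −0.34 and 0.17. The host gene IGF2 was at 0.07 ± 0.11 and did not pass, with probes at 0.19 and −0.06. In the list of the IGF pathway and IGF2 locus, 1 of 12 genes was higher and 2 lower (the same numbers adjusted over the list alone; adjusted p = 0.749 by camera). These were genes of binding proteins: IGFBP7 was at −0.93 ± 0.04, IGFBP4 at −0.37 ± 0.08 (probes −0.65 and −0.08), and IGFBP3 at 0.49 ± 0.04 (probes 0.78 and 0.19). The receptor gene IGF2R, at 0.28 ± 0.12, did not pass. For microRNA processing and silencing, 2 of 11 were higher and 0 lower (2 adjusted over the list alone; adjusted p = 0.407 by camera). These were DICER1 (0.50 ± 0.14) and TNRC6A (0.45 ± 0.0033, probes 0.72 and 0.19). The Argonaute genes AGO4 (0.24 ± 0.04) and AGO1 (0.21 ± 0.06, probes −0.06 and 0.48) did not pass.

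Keratinocyte lists did not pass as a whole. For basal keratinocyte genes, 3 of 15 were lower and 0 higher (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.103 by camera). These were TP63, the transcription factor gene of basal cells (−0.78 ± 0.21), the hemidesmosome gene COL17A1 (−0.56 ± 0.06, probes −0.39 and −0.73) and EGFR (−0.40 ± 0.12). The basal keratin gene KRT5, at −0.36 ± 0.12, did not pass. For suprabasal differentiation, 1 of 20 was higher and 3 lower (2 and 4 adjusted over the list alone; adjusted p = 0.68 by camera). Lower were the keratin gene KRT1 (−0.83 ± 0.07), SPINK5 (−0.79 ± 0.18) and the transglutaminase gene TGM1 (−0.59 ± 0.29). IVL was at −0.41 ± 0.21 and did not pass. In the list of SPRR, S100 and other cornified envelope genes, 3 of 13 were lower and 0 higher (3 lower and 2 higher adjusted over the list alone; adjusted p = 0.796 by camera). Lower were CSTA (−0.49 ± 0.02), S100A2 (−0.44 ± 0.06) and S100A10 (−0.41 ± 0.08). S100A7, at 0.47 ± 0.31, did not pass. Genes of wound-activated keratinocytes and migration split, with 5 of 19 higher and 5 lower (5 and 6 adjusted over the list alone; adjusted p = 0.848 by camera). PTHLH (−1.51 ± 0.12), MMP10 (−1.29 ± 0.31) and KRT6A (−1.24 ± 0.22) were lower, and PLAUR, the urokinase receptor gene, higher (0.95 ± 0.05). Simple epithelial and junction genes split as well, with 5 of 18 higher and 6 lower (7 and 7 adjusted over the list alone; adjusted p = 0.902 by camera). The desmosome genes DSC2 (−0.80 ± 0.15) and DSG2 (−0.71 ± 0.36) and the connexin gene GJB2 (−0.61 ± 0.14) were lower, whereas PKP3, also a desmosome gene, was higher (0.97 ± 0.0070).

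Lists of cell types other than keratinocytes did not pass. For mesenchymal and fibroblast genes, 3 of 17 were higher and 2 lower (3 and 2 adjusted over the list alone; adjusted p = 0.902 by camera). SPARC was at 0.99 ± 0.17, COL1A1 at 0.52 ± 0.06 and CDH2 at −0.85 ± 0.07. FN1 was at −0.47 ± 0.01, and its probes gave −0.17 and −0.77. None of 8 melanocyte genes passed (0 adjusted over the list alone; adjusted p = 0.848 by camera). TYRP1 was at −0.18 ± 0.0089. Of 10 leukocyte and Langerhans cell genes, only CD207 passed as higher (0.42 ± 0.10; 1 adjusted over the list alone; adjusted p = 0.902 by camera). HLA-DRA (−0.43 ± 0.24), CD14 (−0.33 ± 0.35) and ITGAM (−0.27 ± 0.10) did not pass.

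The lists of YAP/TEAD, immediate early, p38, Wnt, Notch and interferon response genes did not pass. The YAP/TEAD target gene CCN2 was higher (1.29 ± 0.14) and BIRC5 (−1.01 ± 0.39), FJX1 (−0.64 ± 0.16) and AMOTL1 (−0.58 ± 0.15) lower. In all, 2 of 18 were higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.945 by camera). The list's median (0.02) and mean (−0.02) differed in sign. BIRC5, the gene of survivin, is also on the mitosis list. Of immediate early and MAPK feedback genes, 4 of 20 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.794 by camera). FOS (1.21 ± 0.40), FOSB (0.79 ± 0.09) and the phosphatase gene DUSP4 (0.61 ± 0.05) were higher, and DUSP6 was lower (−0.62 ± 0.12). In the MAPKAPK2 and p38 pathway, 1 of 15 was higher and 2 were lower (2 and 3 adjusted over the list alone; adjusted p = 0.902 by camera). ZFP36L1 was at 0.38 ± 0.04 and CREB1 at −0.37 ± 0.0066, with probes at −0.60 and −0.14. MAPK13, at −0.34 ± 0.11, did not pass. Of Wnt and beta-catenin targets, 2 of 15 were higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.945 by camera). They were SFRP1 (0.54 ± 0.14), CCND1 and the receptor gene FZD6 (−0.75 ± 0.03). CTNNB1 was at −0.33 ± 0.23 and did not pass. The median of this list was −0.02 and its mean 0.0047. In the Notch pathway, 2 of 12 were higher and 3 lower (2 and 5 adjusted over the list alone; adjusted p = 0.794 by camera). They included the ligand genes JAG2 (−0.57 ± 0.12), JAG1 (−0.37 ± 0.09) and DLL1 (0.35 ± 0.03) and HES2 (−0.34 ± 0.02). The list's median was 0.0054 and its mean −0.08. Of interferon response genes, 3 of 24 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.161 by camera). OAS1 (0.88 ± 0.03, probes 0.71 and 1.04), OAS3 (0.43 ± 0.04) and ISG15 (0.42 ± 0.10) were higher and IFIT1 lower (−0.36 ± 0.06).

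Of p53 target genes, 2 of 19 were higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.902 by camera). PLK3 was at 0.55 ± 0.13, the death receptor genes TNFRSF10B at 0.38 ± 0.05 and FAS at −0.48 ± 0.01, and TP53I3 at −0.38 ± 0.02. Of the BCL2 family and apoptosis genes, 2 of 18 were higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.749 by camera). BMF (0.71 ± 0.03) and CASP9 (0.33 ± 0.0080) were higher and BIK lower (−0.55 ± 0.02). BAX, at 0.37 ± 0.18, did not pass. Among oxidative stress and NRF2 targets, 4 of 13 were higher and 3 lower (5 and 4 adjusted over the list alone; adjusted p = 0.945 by camera). HMOX1 and the ferritin gene FTL (0.56 ± 0.10) were higher and NQO1 (−0.62 ± 0.16) and ME1 (−0.52 ± 0.05) lower. For the unfolded protein response and ATF4 targets, 4 of 21 were higher and 3 lower (6 and 4 adjusted over the list alone; adjusted p = 0.794 by camera). CTH was at 0.80 ± 0.0054, DNAJB9 at 0.68 ± 0.03, DDIT3 at 0.55 ± 0.22 and ASNS at −0.55 ± 0.04 (probes −0.74 and −0.36). The chaperone gene HSP90AA1 (0.89 ± 0.20, probes 1.10 and 0.69) was the only one of 9 heat shock genes to pass (1 adjusted over the list alone; adjusted p = 0.848 by camera). HSPD1 (−0.33 ± 0.25), DNAJB1 (−0.29 ± 0.09) and BAG3 (−0.20 ± 0.01) did not pass. For glycolysis and hypoxia, 1 of 18 was higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.794 by camera). They were PKM (0.35 ± 0.10), NDRG1 (−0.83 ± 0.18) and BNIP3 (−0.65 ± 0.09). ANKRD37, at −0.34 ± 0.08, did not pass. For oxidative phosphorylation, UQCRC1 alone of 20 passed, as lower (−0.37 ± 0.02; 0 adjusted over the list alone; adjusted p = 0.848 by camera). SDHB (0.25 ± 0.05), UQCRFS1 (0.20 ± 0.04) and CYC1 (0.15 ± 0.03) did not pass. For cholesterol synthesis and SREBP2 targets, DHCR7 alone of 16 passed, as higher (0.49 ± 0.11; 1 adjusted over the list alone; adjusted p = 0.956 by camera). SQLE (−0.28 ± 0.03), HMGCS1 (−0.25 ± 0.31) and ACAT2 (−0.20 ± 0.04) did not pass. The median of this list was −0.0004 and its mean 0.0034. Of cytosolic ribosomal protein genes, RPL4 alone of 26 passed, as higher (0.42 ± 0.12; 0 adjusted over the list alone; adjusted p = 0.894 by camera). RPS3 (0.29 ± 0.10), RPS24 (−0.27 ± 0.05) and RPL37 (−0.22 ± 0.02) did not pass.

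**Figure D3:**
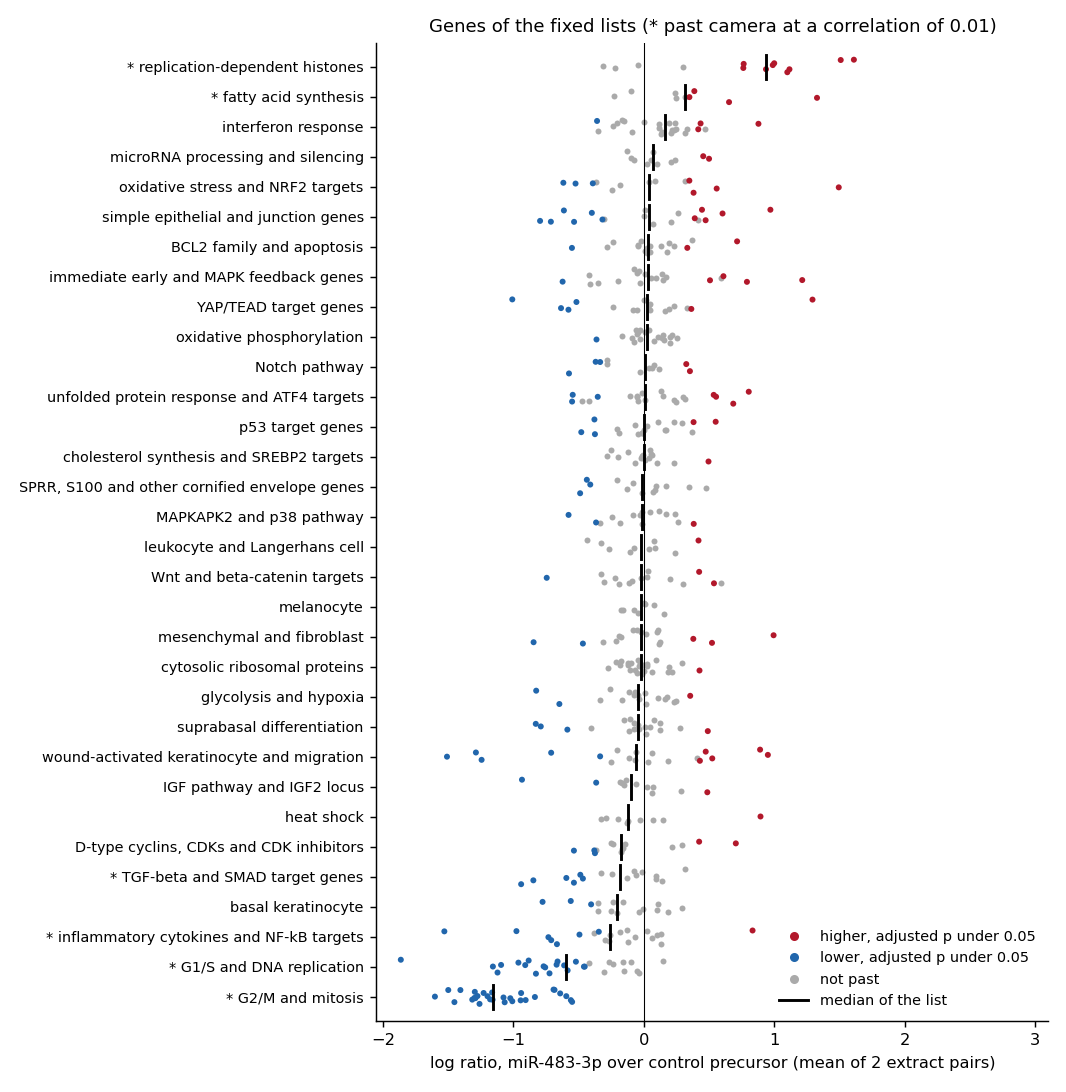
Genes of the 32 tested lists, 1 row per list ordered by its median (black bar), with the log ratio of each gene on the x axis (mean of 2 extract pairs); red and blue points passed an adjusted p of 0.05 as higher or lower, grey points did not, and the vertical scatter within a row has no meaning. The medians run from −1.16 for G2/M and mitosis to 0.94 for replication-dependent histones, and stars mark the 6 lists past camera at a correlation of 0.01.

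The arrays carry 321 spots of ACTB and 272 of GAPDH, spread over 48 runs of 576 features in the order of the table. The first 8 runs hold 24 to 46 ACTB spots each and the other 40 runs 1 or 2. In the first 8 runs the median ACTB spot was at −0.24 (SD 0.121 over 279 spots) and the median GAPDH spot at 0.295 (SD 0.112 over 44 spots). In the other runs ACTB was at −0.60 (SD 0.085 over 42 spots) and GAPDH at −0.05 (SD 0.097 over 228 spots). The values of ACTB and GAPDH thus differed by 0.362 and 0.343 between parts of the arrays, more than the spread of the spots within a part. Leaving out the ACTB and GAPDH spots, these 8 runs hold 15.5% of the named features, but 5 of the 12 largest increases (ISYNA1, H2BC12, KRT23, H1-2 and ATP6AP1) and 2 of the 12 largest decreases (EI24 and ATP6V1B2). SREBF1, TP63, PKP3, SPARC, BNIP3, DUSP6, FJX1, GJB2, HLA-DRA, KRT5, RPL4, RPS3, SMAD4 and SQLE also lie there, as does 1 of the 2 probes of COL17A1, CREB1, HSP90AA1, IGF2 and JAG1.

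**Figure D4:**
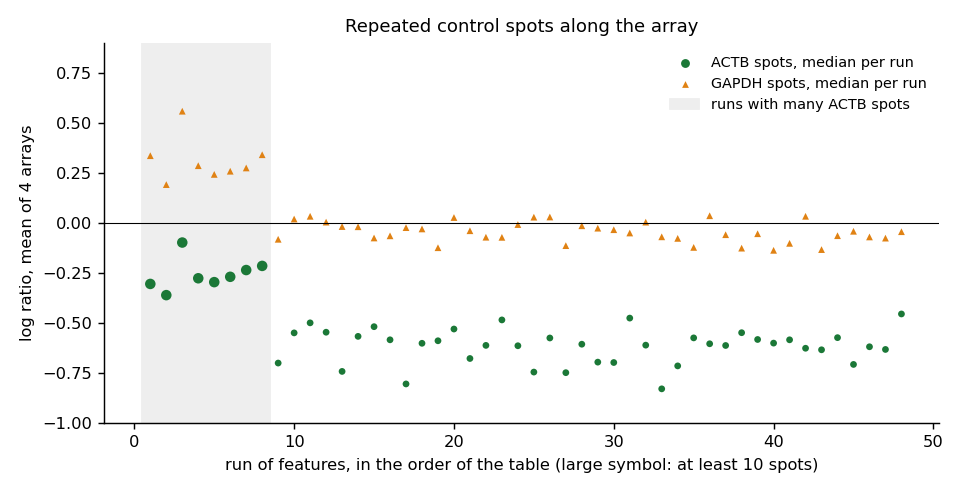
Median log ratio (y axis, mean of 4 arrays) of the ACTB spots (circles) and the GAPDH spots (triangles) in each of 48 runs of 576 features in the order of the table (x axis); large symbols stand for at least 10 spots, and shading marks the 8 runs with 24 to 46 ACTB spots. The medians over the shaded runs exceed those over the others by 0.362 for ACTB and 0.343 for GAPDH.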

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

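The alternatives that leave out the first 8 runs of features, include unnamed features, leave out genes whose arrays span over 1 log2 unit, block the extract pair or estimate the correlation on 4 arrays were chosen after seeing the data. Of the named genes past the threshold, 0 changed sign under the scalings, the fits of 4 arrays, the single orientations or without either extract pair; probes of a gene that differ by more than 0.3 or in sign are given with the gene. Of those not past it, 3 did: CDC25A and CTNNBIP1 with Cy5 only (0.085 and 0.1951) and without extract pair 2 (0.0418 and 0.1274), and IGF2 without extract pair 2 (−0.0094). Without either extract pair, the median changed sign for 0 of the 6 lists past camera and for 7 of the others (YAP/TEAD target genes −0.0292, melanocyte 0.0055, cholesterol synthesis and SREBP2 targets 0.0072, MAPKAPK2 and p38 pathway 0.0201, IGF pathway and IGF2 locus 0.0334 and Notch pathway −0.0736 without pair 1, and oxidative stress and NRF2 targets −0.1349 without pair 2). The cause was not tested. With the replicate block for the paired arrays (correlation 0.0975, a trimmed mean over genes, because duplicateCorrelation gave no value for 4 arrays with a dye term) 1351 genes were higher and 1247 lower, and without it 1527 and 1373. Setting each array's median to 0 (1096 and 1082), scaling to the same median absolute deviation (1170 and 1125), robust eBayes (1235 and 1189) and leaving out the first 8 runs (782 and 839) stayed within 1.5 times the counts of 1061 and 1029. The counts moved further with only the arrays with miR-483-3p in Cy5 (569 higher; 807 lower is within that range) or in Cy3 (557 and 463), where 41.4% and 54.6% of calls were higher against 50.8% with both. They also moved without genes whose arrays span over 1 log2 unit (1943 and 1743) and at an adjusted p of 0.10 (1707 and 1597). Single orientations keep any constant dye effect and the wider threshold passes more genes by construction; other causes were not tested. The 2-fold counts of 64 and 129 became 106 higher in Cy3 only and 367 and 462 at 1.5-fold, and ranged from 73 to 86 and from 153 to 156 without either extract pair. Of the 150 named genes, 30 lost their call with Cy5 only and 40 with Cy3 only. In the fit of 4 arrays with the replicate block 2 lost it and 9 gained one, and without the block 1 and 11. Setting medians to 0 and scaling to the same median absolute deviation gave a call to 2 and 4 more. Of the 6 lists past camera at a correlation of 0.01, 4 passed with Cy5 only and 3 without the first 8 runs (G2/M, G1/S and histones). Without these runs the medians of the others went from −0.2641 to −0.2154 for inflammation, from −0.186 to −0.2421 for TGF-beta and from 0.314 to 0.2786 for fatty acid synthesis. With an estimated correlation 0 passed on the extract-pair means (0 of all 32 lists at an unadjusted p under 0.05). On 4 arrays 0 passed as well (2 of all 32 lists unadjusted). With fry's directional p 0 passed (10 of all 32 lists unadjusted). Of all 32 lists, 22 passed fry's mixed p. G2/M and mitosis was not among them (adjusted p = 0.0511 by fry's mixed test), while cholesterol synthesis and SREBP2 targets was (0.0412). On 2 extract-pair means, 1 residual degree of freedom limits the estimated correlation and fry. No value was missing, so the alternative on missing values moved nothing. With 1 extract pair left out the tests have no residual degrees of freedom and give no call. The seed-site alternatives were not run, since 3' UTR sequences were not used here. No background or intensity values were used, so what dim signal limits is unknown.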

Other observations

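Only the alternative without the first 8 runs had its bounds set before its outcome was seen; the runs themselves, the other tests, the gene families and the genes named here were chosen after the values were seen. MUC4, MUC16 and MUC20 followed PGM2L1 among the increases, but MUC genes did not pass as a family. Of 17 genes with MUC symbols, 4 were higher and 0 lower, with a family median of −0.01 (adjusted p = 0.739 by camera over 276 symbol families). The fourth, MUC1, was at 0.71 ± 0.06 (SD, n = 2), but its probes disagreed, at 1.53 and −0.11. The probe at 1.53 lies in the first 8 runs, where the control spots read higher, and the other does not. Further increases, picked by eye and with no test as a group, were the keratin gene KRT20 (1.40 ± 0.15), GNE, whose enzyme starts sialic acid synthesis (1.39 ± 0.0037), DMBT1 (1.27 ± 0.35), the epithelial transcription factor gene ELF3 (1.20 ± 0.12), the matrix metalloprotease gene MMP7 (1.20 ± 0.09) and S100P (1.16 ± 0.02).

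Kinesin genes were the single symbol family of 276 past the adjusted threshold. Of 31 KIF genes, 12 were lower and 2 higher (adjusted p = 0.0155 by camera; unadjusted p = 0.136 with an estimated correlation on the extract-pair means and 0.0434 on 4 arrays). Of the 28 on no fixed list, 9 were lower, among them the mitotic motor genes KIF2C (−1.20 ± 0.24), KIF15 (−1.14 ± 0.13) and KIF4A (−1.07 ± 0.01). KIF13B (0.84 ± 0.11) and KIF2A (0.34 ± 0.05) were higher. Further decreases outside the lists were ODC1, the gene of the enzyme that starts polyamine synthesis (−1.49 ± 0.07), the centromeric histone gene CENPA (−1.48 ± 0.19), RAN (−1.39 ± 0.05) and the lamin gene LMNB1 (−1.11 ± 0.10).

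The 57 measured genes on the G1/S and mitosis lists had a median of −0.884. Normalization in the first 8 runs is argued against by the 52 of these genes measured outside them, whose median was −0.908. Dye bias as the whole cause is argued against as well. The median was −0.929 with miR-483-3p in Cy5 and −0.832 with it in Cy3, and in turned ratios dye bias needs opposite signs. The sources do not say that the ratios were turned. Had they not been, effects of the RNA would lie in the dye-dependent part, where camera passed 0 of 32 lists (2 at an unadjusted p under 0.05). Dye bias would then have had to follow gene function, since 47 of these 57 genes (82.5%) passed as lower, against 7.08% of all genes. An effect of the transfected miR-483-3p, which the design names, stays open as well and was not tested further.

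The 13 measured genes of the histone list had a median of 0.935, above that of the wider set. Among all 60 measured replication-dependent histone genes, 19 were higher and 2 lower, with a median of 0.171 and class medians of −0.05 for H1 and 0.0064 for H3. Each of the 5 classes (H1, H2A, H2B, H3 and H4) held at least 1 gene that was higher, though H3 held only 1 of 9. Over all genes 1061 of 14533 were higher, so 1 such gene in a class says little. H1 (2 of 6), H2A (6 of 15), H2B (6 of 17) and H4 (4 of 13) held larger shares. These shares argue against cross-hybridisation within a single class as the whole cause. Cross-hybridisation within each of several classes was not tested and stays open. The median of the 11 list members outside the first 8 runs was 0.764, which argues against normalization there as the whole cause. Fewer cells in S phase would lower these mRNAs, and the list's median goes the other way, but that explanation stays open. The way the RNA was primed for labelling is not given in the sources used here, and a change in the polyadenylated share of histone mRNA would count in the value. The list's median was 0.76 with miR-483-3p in Cy5 and 1.035 with it in Cy3, which argues against dye bias as the whole cause if the ratios were turned. The sources do not say that they were. In unturned ratios equal signs cannot tell dye bias from an effect of the RNA, and genes of a class share sequence. Turning concerns whole arrays, however, and the cell-cycle values above argue against unturned ratios. Of those genes 82.5% passed as lower, against 7.08% of all genes, and 0 of 32 lists passed camera on the dye-dependent part. Dye bias as the whole cause is thereby argued against for the histone list too.

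The controls differ between parts of the arrays. If the ratios were turned, a dye bias by position is argued against. It would then give opposite signs, whereas GAPDH was higher in the first 8 runs in both orientations, by 0.299 and 0.403. In unturned ratios such a bias would give equal signs. The cell-cycle values above (82.5% lower, against 7.08% of all genes) argue against unturned ratios, and so against this bias as the whole cause. A candidate explanation is a normalization within parts of the array that the many ACTB spots, themselves low, pulled upwards at their brightness. It needs GAPDH to rise with ACTB there, and GAPDH was higher by 0.343. Of the other features there, 9.58% were called higher, against 6.91% elsewhere, but those called lower made up about as large a share (6.87% against 6.93%), so this explanation stays open. Different probe sequences under the same control names stay open, since probe sequences were not used here.

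The feature with the largest dye-dependent part, unnamed, changed sign with the dye orientation, with log ratios of −5.17 and −5.46 with miR-483-3p in Cy5 and 5.75 and 5.89 in Cy3, and its neighbours in the table had the same alternation: the 3 features before it (SLC66A1, ABI3BP and PBOV1), with dye-dependent parts of −2.69, −1.86 and −0.85, and the unnamed feature after it, with −0.66. Over all genes, 0 had a dye-dependent part past the adjusted threshold by limma, with 2371 at an unadjusted p under 0.05. Of the 9937 unnamed features, 42 were at least 2-fold changed with the same sign on all 4 arrays.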
